A study of Medicago truncatula and Arabidopsis thaliana with 50 samples.

How the data were processed

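The series holds 50 sequencing libraries from Medicago truncatula and Arabidopsis. They fall into 42 small RNA libraries, 6 PARE libraries, which sequence the 5′ ends of cleaved or decapped polyadenylated RNA, and 2 polyadenylated RNA libraries. Medicago hairy roots carried overexpression constructs (OX) for miR1507, miR2109, miR2118a, miR2118b or miR2118c, or target mimics (MIM), which are transcripts that sequester a miRNA, against miR1507, miR2109, miR2118 or all of them. Arabidopsis leaves carried the same 5 overexpression constructs. Each construct and each of the 3 controls had 2 libraries. The 8 untransformed Medicago tissues and the 6 PARE samples had 1 library each. The labels do not say whether replicates were separate plants, separate transformations or repeated library preparations.

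Small RNA libraries were prepared with the TruSeq small RNA kit and sequenced on a HiSeq 2000, per the labels. The deposited files list each distinct sequence with its raw count of reads, and the values were whole numbers with no normalization. Adapter trimming and length selection were done by the authors before deposit. Reads of 18 to 34 nt were listed for small RNA, 18 to 20 nt for PARE and 18 to 51 nt for polyadenylated RNA. No trimming tool, aligner or genome build is given in the sources used here. The sequence-count files carry no gene names, and the reference table of gene symbols was not used because no read could be placed on an annotated gene without a genome.

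Depth was taken as the sum of counts per library. Small RNA libraries held 11.2 to 48.3 M reads (M for mega), PARE libraries 24.5 to 34.1 M, and polyadenylated RNA libraries 8.3 and 18.4 M. Counts per M reads (CPM) were computed here from those counts with trimmed mean of M values (TMM) factors. Values of single libraries are reads per M reads of the library (RPM) with exact Poisson intervals at the 95% level. Intervals and detection floors cover counting error only, because reads carry no molecular identifiers. P-values measure only the spread between the sequenced samples, which can be technical.

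Because no genome could be used, the tests planned for annotated genes were replaced, as foreseen before the data were examined, by tests on single sequences of 20 to 24 nt with at least 10 reads in a series. Tags of listed miRNA families were summed into 1 feature per family. A tag of up to 23 nt joined a family with at most 2 mismatches over positions 2 to 19 for the 4 studied families, counted from the 5′ end, and at most 1 for the others. Of the 35 families, 34 were listed before the data were examined. The miR2109 and miR2118b families were taken with their leading sequences in the reads, which was chosen after the data were seen.

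A finer level was added after the data were seen. The polyadenylated RNA reads of the 2 overexpression controls were assembled into fragments with k-mers of 25 nt, each seen in at least 2 reads, and fragments of 100 nt or more were kept. This gave 73763 fragments with 22.8 M bases, an N50 of 454 nt and a longest fragment of 9812 nt. Of the reads, 47.1% and 45.3% matched 1 place in the assembly. Strand was assigned to 65036 fragments with at least 10 PARE tags of which at least 80% lay on 1 strand. Small RNA reads of 21 nt outside the listed families were counted on a fragment where they matched exactly and at 1 place. Fragments are named c followed by their rank in length. Identities are given as what a translated frame reads like, from known protein motifs, since no annotation could be searched. A fragment of a gene family can take reads from a near-identical paralog that was not assembled, so the source of each read is uncertain within a family.

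Fragments with a conserved nucleotide-binding (NBS) motif were found in all frames with fixed patterns: 166 fragments, of which 39 had a P-loop, 90 a GLPL motif and 43 a kinase-2 motif. The gene lists written by product name before the data were examined were not run, because they need an annotation, and the NBS patterns took their place after the data were seen. The rules for predicted targets and phased loci were written before, and were applied to fragments only after. Lists of 43 fragments with a TIR motif, 12 with a kinase-2 motif ending in D or N and 9 with one ending in W were chosen after the called fragments were seen. So were the lists of fragments called higher in overexpression, which were asked of the mimic libraries. Target sites were predicted with a mismatch costing 1 and a G:U pair 0.5, doubled at miRNA positions 2 to 12, and a score of at most 4. This gave 6 fragments for miR1507, 2 for miR2109 and 8 for miR2118. Cleavage was read between the bases opposite miRNA positions 10 and 11.

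Phased loci (PHAS) were called in the pooled 8 untransformed tissues from windows of 10 cycles of 21 nt, with a hypergeometric p of at most 1e-06 and at least 10 distinct positions. Reads of the minus strand were shifted by 2 nt. Of 2600 fragments with enough positions, 21 passed.

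Differences were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. All groups of a series entered 1 fit with 1 coefficient per group and no covariate: 12 Medicago overexpression libraries, 10 mimic libraries and 12 Arabidopsis libraries. Overexpression and mimic were compared as a difference of changes in 1 fit of 22 libraries. The fits tested 1791 fragments and 201142 sequences in overexpression, 1556 fragments and 188069 sequences in the mimics, and 50725 sequences in Arabidopsis. The biological coefficient of variation was 0.362 for fragments and 0.492 for sequences in overexpression, 0.463 and 0.698 in the mimics, and 0.197 in Arabidopsis. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, beside camera with an estimated correlation and fry. Medians of lists are of those voom fits, or of edgeR where called fitted. Folds against a group with no reads are given as lower bounds against a floor of 3 counts per library. For the PARE libraries, which have no replicates, a list median of log2 ratios with 0.5 tags added was placed among 10000 random lists of positions with at least 10 tags, matched on mean level. Other computing used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

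The named items follow a rule written before the data were examined. For each Medicago construct it takes, among called fragments whose 2 libraries lay on the same side of both controls, up to 6 predicted targets of the construct's miRNA, up to 6 other NBS fragments and up to 4 others, each by largest absolute log2 change. The 10 phased loci with most 21-nt reads in the untransformed tissues are given for every construct. For Arabidopsis it takes the listed families past the threshold and up to 4 other sequences, and for single libraries the top 10 by level. After the data were seen, fragments with under 2 reads over the 8 untransformed tissues, and Arabidopsis sequences with reads in Medicago libraries, were left unnamed.

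Pairing by replicate number was checked from deviations from group means. Same-numbered libraries correlated by sequences at 0.227 to 0.624 over 15 pairs of overexpression groups and at 0.239 to 0.777 over 10 pairs of mimics. The numbers pair those libraries by sequences, but not all by fragments. Sequencing runs are not in the labels. Substitution errors of 1 abundant miRNA sequence, TCGGACCAGGCTTCATTCCCC, separate the libraries into sets by the rates of C7A, T12A, T12G, T16G and T17G, with positions counted from the 5′ end. By these rates replicate 1 and replicate 2 of the overexpression and mimic series came from different runs. The exception, miR2118c OX 2, stood alone in its series, and a replicate block counts it with replicate 2. In Arabidopsis both controls, both miR1507 OX libraries and miR2118b OX 2 shared 1 run, and the other 7 libraries shared another. Sets were formed within each series. In T12A, T12G and T16G the Medicago library miR2118c OX 2 lay within the range of those 7 Arabidopsis libraries, and in C7A and T17G above it. Whether they shared a run was not tested. Untransformed leaves, roots, seedlings and flowers formed 1 set, and the nodule and denodulated-root libraries another.

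Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors, library totals, no filter, only the 2 groups compared, a replicate block, each library left out in turn, reads with up to 20 places weighted, 21 and 22 nt, antisense reads, other target scores, other phasing thresholds and a 3-nt cleavage window. A run term, the mimic fits without 2 libraries and the list tests with a block were added after the data were seen.

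Every step that computes a statistic over many features was tested on simulated data. With 100 of 1606 fragments changed 4-fold in miR1507 OX, 54 were recovered, and with 16-fold changes 85, with 5 false calls over both sets. In MIM miR1507, over 1426 fragments, 38 and 81 were recovered with 4 false calls. In Arabidopsis miR1507 OX, over 47747 sequences, 63 and 88 were recovered with 15 false calls. In Medicago miR1507 OX and MIM miR1507, 0 of 100 changed sequences were recovered at either fold, over 178069 and 164186 sequences. Counts of 0 at that level in those comparisons say nothing about absence. Of 200 sets of phased positions 200 passed and of 2000 unphased sets 0 did, and 200 of 200 planted target sites were found.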

Results

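Small RNAs were sequenced from Medicago truncatula (Jemalong A17) hairy roots, from untransformed Medicago tissues and from Arabidopsis leaves. The study concerned 22-nt miRNAs that target transcripts of NB-LRR genes, which encode nucleotide-binding leucine-rich-repeat immune receptors, and the secondary 21-nt siRNAs made in register after cleavage. In the Medicago overexpression series, 6 groups of 2 libraries (5 constructs and a control) held 15.8 to 35.8 M reads (M for mega) per library. The mimic series had 5 groups of 2 libraries (4 mimics and a control) with 31.2 to 38.8 M reads. The Arabidopsis series had 6 groups of 2 libraries with 16.5 to 27.7 M reads. The 8 untransformed tissues had 1 library each with 11.2 to 48.3 M reads. The 6 PARE libraries held 24.5 to 34.1 M reads, 1 for each overexpression group and the control, and the 2 polyadenylated RNA libraries of the overexpression control held 8.3 and 18.4 M. Loci are transcript fragments assembled from those 2 libraries, and fold changes are log2 with their standard error (SE).

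In untransformed plants the studied miRNAs were abundant in vegetative tissue, except miR2109, which was highest in flowers. Each tissue had 1 library, so the values carry counting intervals and no test. The miR1507 family stood at 1330 RPM (reads per M reads of the library) in roots (1320 to 1350) and 1230 in seedlings but at 6.21 in flowers (5.53 to 6.96). The miR2118 family stood at 5810 in leaves, 4040 in seedlings and 0.87 in flowers (0.627 to 1.18). The miR2118b family reached 2170 in seedlings and 0.994 in flowers. The miR2109 family had 1180 in flowers (1170 to 1190) and 76.7 in 14-dpi denodulated roots (73.1 to 80.4). The ratios of highest to lowest tissue were 214 for miR1507, 15.4 for miR2109, 6680 for miR2118 and 2180 for miR2118b. Among all listed families miR166, a regulator of HD-ZIP III transcription factors, was highest in 7 tissues, with 123000 in roots, and miR172, which targets APETALA2-like transcripts, led in flowers with 10900 against 0.169 in seedlings. Some of the fragments with most 21-nt reads were nearly single-sequence loci. Of the 21-nt reads on c58583, which led in leaves with 12500 RPM, 95.7% were 1 sequence, and for c60479, which led in seedlings with 13000 and in roots with 5500, the share was 94.3%. Fragment c27551 led in all 4 nodule and denodulated-root libraries with 2100 to 6890 RPM, and c3356 and c51676 led in flowers with 10300 and 8710, with a share of 38.2% for c3356.

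Phased 21-nt siRNAs came from NB-LRR fragments and from other gene classes. Pooling the 8 untransformed libraries and testing phasing in windows of 10 cycles found 21 phased fragments among 2600 with enough positions, of which 4 carried an NBS motif and 4 a predicted site of a studied miRNA with a score of at most 5. The assembly covers transcripts of control roots, so loci of other tissues were largely out of reach. The locus with most reads, c365 (2302 nt, p 2.9e-08), has a frame that reads like a TIR1/AFB auxin-receptor F-box protein, a class known to yield phased siRNAs. It had 58.3 RPM in leaves and 0.97 in seedlings. Fragment c14947 (387 nt, p 8.5e-12) reads like an APETALA2-like factor, with 30.1 in leaves and 0.145 in flowers. Fragments c5429 (792 nt, p 5.2e-07), c16609 (356 nt, p 5.8e-09) and c6652 (701 nt, p 5.9e-11) read like TIR-class NB-LRRs. The first had 12.2 in leaves, 9.69 in flowers and 0.127 in seedlings, and the second 5.64 in roots and 0.759 in seedlings. Fragments c23445 (p 3.3e-07) and c19985 (p 8.5e-09) carry a kinase-2 motif of the class without a TIR domain. Fragment c39269 reads like the nucleotide-binding domain of the same class and had 4.98 in seedlings and 0.0323 in leaves. Of the other leading loci, c2827 reads like an aldo-keto reductase, c20462 like a cinnamyl-alcohol dehydrogenase (3.25 in flowers), and the frame of c1381 was not recognized. Further down, c9145 reads like a CONSTANS-like factor, c641 like a CIPK kinase, c887 like a Dicer, the enzyme that makes siRNAs, and c1823 like an AMP deaminase. In polyadenylated RNA of control roots the median fragment stood at 1.49 RPM, NBS fragments at 1.79 and phased fragments at 7.45. The levels were 53.8 ± 3.25 for c641, 50.5 ± 3.24 for c1823, 49.7 ± 4.16 for c365, 37.9 ± 7.96 for c20462, 7.45 ± 1.01 for c5429 and 2.81 ± 0.264 for c16609 (SD, n = 2). Highest in reads were c1, the longest of the assembly, with 232 ± 164, and c122, with 205 ± 15.9. Of the NBS list c49, which entered by a GLPL match alone, had most, with 108 ± 19.6.

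Each overexpression construct in Medicago roots raised its own miRNA family, the only listed family called in it adjusted over the list alone. The question was whether the label of each library matched its miRNA, tested with edgeR over 27 families. With 2 libraries per group, the changes in the fit without a block passed the threshold adjusted over the list alone and not over all 201142 sequences. With the replicate number as a block the adjusted p over all sequences was 0.0113 for miR1507, 0.00718 for miR2109, and 0.0061, 0.000392 and 0.00628 in miR2118a, b and c OX. The miR1507 family stood at 34100 ± 28500 CPM against 1250 ± 687 in the control (SD, n = 2), a change of 4.76 (SE 1.08) with an adjusted p of 0.0203 over the list alone and 0.122 over all sequences. The miR2109 family stood at 4090 ± 2550 against 173 ± 2.94, a change of 4.56 (SE 0.85, 0.00381 adjusted over the list alone, 0.115 over all). In miR2118a OX the miR2118 family changed by 4.37 (SE 0.78, 0.00271 adjusted over the list alone, 0.116 over all) and in miR2118c OX by 3.54 (SE 0.75, 0.0123 adjusted over the list alone, 0.124 over all). The miR2118b family changed by 7.19 in miR2118b OX (SE 1.19, 0.00127 adjusted over the list alone, 0.0611 over all), from 24.6 ± 15.8 to 3580 ± 3350 CPM. The miR2109 family in miR2118c OX stood at 382 ± 58.7 against 173 ± 2.94, a change of 1.14 (SE 0.74) that was not called (0.944 adjusted over the list alone), with both libraries above both controls. Among the families 1 was called higher in each construct adjusted over the list alone and 0 over all sequences. In edgeR without adjustment all 5 had p under 0.05, from 4.71e-05 for miR2118b to 0.000751 for miR1507, and DESeq2 gave adjusted p of 6.35e-07 or lower for all 5, the lowest of a range over the alternatives that reached 1.0 for each.

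**Figure D1:**
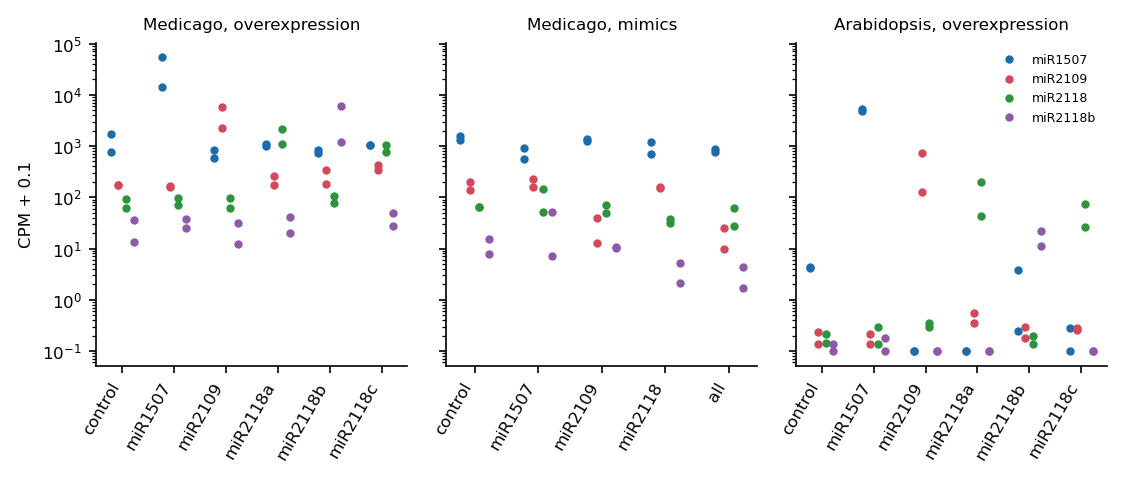
CPM plus 0.1, on a log axis, of the 4 studied miRNA families in each library of the Medicago overexpression, Medicago mimic and Arabidopsis overexpression series, with 1 point per library and groups along the horizontal axis. The miR1507 family averaged 34100 in Medicago miR1507 OX against 1250 in its control, and 5070 in Arabidopsis miR1507 OX against 4.16.

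Overexpression of miR1507 raised 21-nt siRNAs on 107 fragments, of which 4 had an NBS motif, as did 77 of the 1791 tested. miR1507 is known to target the kinase-2 region of NB-LRRs that lack a TIR domain. The test was edgeR on 21-nt reads per fragment against the control, in which 1 fragment was lower (251 at an unadjusted p under 0.05, 122 by DESeq2), and 93 of the 107 also had reads in untransformed tissue. Leaving out OX control 2 lowered the count to 54. The largest NBS change was on c19985, which was also phased in untransformed tissue: 42.4 ± 31.0 CPM against 1.65 ± 0.473, a change of 4.67 (SE 0.57, adjusted p 0.000631). It carries a miR1507 site with a score of 4.5, over the limit used for the target list. Fragments with a GLPL motif rose as well, c71010 by 4.29 (SE 0.45, 0.000294), from 0.279 to 5.63 ± 0.391 CPM, c59736 by 3.76 (SE 0.34, 0.000275), from 0.465 to 6.33 ± 1.49, and c46901 by 3.82 (0.00914). Of fragments outside the NBS list, c49015, which reads like leucine-rich repeats, rose by 5.72 (SE 0.93, 0.00258), c59153 by 5.48 (0.00728), c14336, which reads like the C-terminus of a GH3 auxin-conjugating enzyme, by 5.17 (0.00152), and c41040, which reads like a nucleotide-binding domain, by 4.87 (0.00398). The call on c46901 was lost without OX control 1 (adjusted p 0.0786) or miR1507 OX 1 (0.079), on c59153 without miR1507 OX 1 (0.105), and on c41040 without OX control 2 (0.0569) or miR1507 OX 1 (0.0551). Among the 10 leading phased loci none was called, with changes from -0.83 on c1381 to 0.33 on c23445 and adjusted p from 0.348 to 0.984. Of single sequences 597 were higher and 42 lower (10240 unadjusted, 1368 by DESeq2, 3761 with the replicate block). Without OX control 1 or without OX control 2 that count was 0, and without miR1507 OX 1 or 2 it was 251 or 348.

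Overexpression of miR2109 raised siRNAs on a set of fragments of which 18 of 87 carried a TIR motif, from the part of TIR-class NB-LRRs that this miRNA is known to target. In edgeR 87 fragments were higher and 1 lower (210 unadjusted, 99 by DESeq2), and all 87 had reads in untransformed tissue. The count was 52 without OX control 2 and 58 without miR2109 OX 1. Fragment c1381, a phased locus, rose by 4.80 (SE 0.37, adjusted p 4.52e-05), from 0.615 to 17.2 ± 3.95 CPM. Fragment c66757, whose frame reads like a TIR domain, rose by 4.86 (SE 0.69, 0.000902), from 0.471 to 13.6 ± 0.972, and c23614, with a TIR motif, by 4.87 (0.000902). Fragment c8214 had 30 and 38 reads against 0 and 0 and was at least 13.8-fold higher (adjusted p 0.0184, lost without OX control 1 at 0.065 and without miR2109 OX 2 at 0.109, and 0.91 by DESeq2). Of NBS fragments 5 of 77 tested were higher, and 43 lay below 0. The P-loop fragment c45597 rose by 3.11 (SE 0.41, 0.000753), from 0.63 to 5.53 ± 0.733 CPM. Of weaker calls, c67453 rose by 3.22 (0.0444), c43087 by 1.82 (0.0112), c29982 by 1.57 (0.0226) and c57124 by 1.43 (0.0439). Each of these 4 calls was lost under such a change: c67453 with the replicate block (0.0532), only the 2 groups (0.0592) or no filter (0.103) or without OX control 2 (0.251), miR2109 OX 1 (0.163) or miR2109 OX 2 (0.187), c43087 with no filter (0.46) or antisense reads only (0.222) or without OX control 1 (0.136), OX control 2 (0.16) or miR2109 OX 1 (0.0632), c29982 with no filter (1.0) or without any 1 of the 4 libraries (0.0982 to 0.232), and c57124 with library totals (0.0615) or no filter (1.0) or without OX control 1 (0.136), OX control 2 (0.498) or miR2109 OX 1 (0.392). The other leading phased loci had changes from -0.78 to 0.33 and were not called (0.735 to 0.999). At the level of sequences edgeR called 0, with 5974 at an unadjusted p under 0.05, 501 by DESeq2 (466 higher, 35 lower), 880 with the replicate block and 165 with library totals (163 higher, 2 lower).

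Each of the 3 miR2118 constructs raised siRNAs on some NB-LRR fragments, while 46 and 39 of the 77 tested NBS fragments lay below 0 in miR2118b and miR2118c OX. miR2118 is known to target the P-loop of both NB-LRR classes. The tests were edgeR against the control and, for differences between constructs, direct contrasts that do not use the control. In miR2118a OX 87 fragments were higher and 1 lower (200 unadjusted, 80 by DESeq2), and 11 of the 87 had an NBS motif. In miR2118b OX 65 were higher and 4 lower (165 and 70), with 9 NBS fragments among the higher, and in miR2118c OX 69 were higher and 1 lower (178 and 70), also with 9. Leaving out OX control 1 or 2 lowered these counts to 44 or 31 for miR2118a, 45 or 39 for miR2118b and 46 or 44 for miR2118c, and miR2118c OX without replicate 2 gave 46. Within replicate 1 and replicate 2 the median change of the higher fragments was 2.54 and 2.21 for miR2118a, 2.69 and 2.51 for miR2118b and 2.76 and 3.19 for miR2118c, as against 2.79 and 2.32 for miR1507 and 2.5 and 2.43 for miR2109. For miR2118a OX, sequences gave 0 calls (5304 unadjusted, 403 by DESeq2, of which 81 were lower, 687 with the replicate block, and 127 higher and 15 lower with library totals). For miR2118b OX, 90 sequences were higher and 0 lower (4833 unadjusted, 462 by DESeq2, 905 with the block), and for miR2118c OX 360 were higher and 2 lower (8313 unadjusted, 758 by DESeq2, 3266 with the block). For miR2118b the count was 0 to 2 whichever library was left out, and for miR2118c it was 0 without either control, 74 without miR2118c OX 2 and 570 without miR2118c OX 1.

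In miR2118a OX the fragments with siRNA gains included 3 of the 10 leading phased loci. Fragment c6652, a TIR-NB-LRR-like phased locus, rose by 3.19 (SE 0.37, adjusted p 0.000902), from 5.10 ± 0.792 to 46.4 ± 9.61 CPM. The phased loci c2827 and c39269 rose by 4.98 (SE 0.68, 0.00133) and 2.62 (SE 0.39, 0.00201). Of NBS fragments, c12322, with a GLPL motif and a frame holding LLMLDDLW, which the kinase-2 pattern did not take, rose by 5.32 (SE 0.67, 0.00104), from 0.402 to 16.2 ± 12.0. The fragments c33804, with 3.92 (0.00195), and c3740, with 2.73 (SE 0.41, 0.00196) and a level of 11 ± 0.944 CPM against 1.65, also rose, as did c45749 by 4.22 (0.00398), c9661 by 3.68 (0.0065) and c45210 by 3.01 (0.00495). Outside the NBS list, c68657, which reads like the end of a nucleotide-binding domain, was at least 10.1-fold higher (0.00149), c70078, with a P-loop-like frame, at least 6.33-fold (0.00574), and c25532, which reads like leucine-rich repeats, at least 4.67-fold (0.0129). Fragment c70077 rose by 6.03 (0.00545). Single libraries decided 7 of these calls. Without miR2118a OX 1 the adjusted p was 0.123 for c45749, 0.103 for c9661, 0.071 for c45210, 0.0823 for c70078, 0.187 for c25532 and 0.125 for c70077. With only the 2 groups it was 0.0569 for c45210, 0.0599 for c25532 and 0.0549 for c70077. Without OX control 2 it was 0.0683 for c9661, 0.0756 for c45210, 0.0587 for c70078, 0.119 for c25532, 0.0545 for c70077 and 0.0527 for c39269. Without OX control 1 it was 0.071 for c45749, 0.136 for c9661, 0.0794 for c70078 and 0.165 for c25532.

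In miR2118b OX the largest gain of any construct on a phased locus lay on c20462, which rose by 7.71 (SE 0.43, adjusted p 1.53e-06), from 0.547 ± 0.0686 to 116 ± 20.5 CPM. The phased kinase-2 fragment c23445 rose by 3.74 (SE 0.38, 0.000135), to 21.7 ± 4.55. The P-loop fragment c63892 rose by 6.15 (SE 0.71, 0.000344), the kinase-2 fragment c46137, whose motif ends in W as in CC-class receptors, by 5.34 (SE 0.5, 0.000135), c9661 by 4.82 (0.000841), c40493 by 3.38 (0.000859) and c26437 by 2.38 (0.000904), to 24.2 ± 1.65. Fragment c68739, with a frame holding LVVLDDIW, was at least 11.8-fold higher (0.00148). Fragments c69849 and c18466 rose by 5.95 (0.000151) and 5.87 (0.000135).

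In miR2118c OX the gains included 5 fragments with a kinase-2 motif ending in D or N, and none with a TIR motif, among 69. The predicted target c16609, a phased P-loop fragment, rose by 5.31 (SE 0.43, adjusted p 3.95e-05), from 2.51 ± 0.0134 to 99.4 ± 20 CPM, and the predicted target c38502 by 5.26 (SE 0.51, 8.49e-05), from 0.227 to 9.38 ± 0.531. The phased fragment c5429, with all 3 NBS motifs, rose by 4.18 (SE 0.47, 0.000181), from 5.76 ± 1.17 to 105 ± 27.2. Fragments c21358 and c14924 rose by 4.69 (SE 0.53) and 4.22 (SE 0.48), both with 0.000181, to 53.9 ± 14.3 and 99.6 ± 37.2 CPM. The kinase-2 fragments c45123, c20266 and c66372, whose motifs end in D or N as in TIR-class receptors, rose by 4.69 (0.00137), 4.15 (0.000163) and 3.74 (0.000207). Outside the NBS list c18347 rose by 6.03 (0.000134) and c3441, which reads like a nitrate or peptide transporter, by 5.99 (0.000438). Fragment c70907 was at least 8.6-fold higher (0.00422, 0.0754 without miR2118c OX 2) and c69528 at least 3.25-fold (0.0228, and 0.0726 to 0.239 without any 1 of the 4 libraries). The phased fragment c23445 lay at -1.45 and was not called (0.0584), but was with the replicate block (0.0403).

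**Figure D2:**
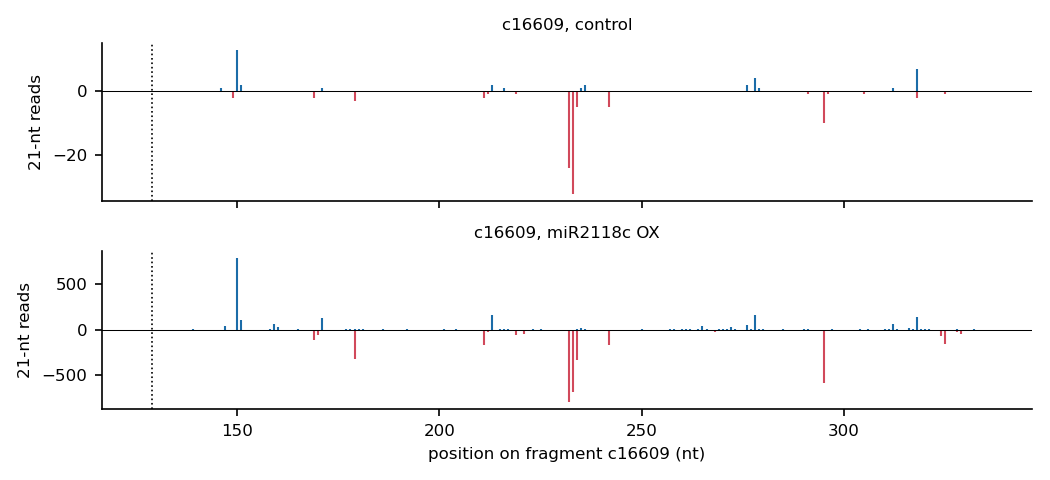
The 21-nt reads along fragment c16609 by their leftmost base (nt, horizontal axis), the 5′ end of sense (blue) and 3′ end of antisense reads (red). The vertical axis gives reads summed over the 2 control or the 2 miR2118c OX libraries. The dotted line marks the predicted cleavage position 129, after which 49.6% of the reads in miR2118c OX lay in the 21-nt register of that position.

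The direct contrasts between miR2118 constructs called many fragments in each direction. Between miR2118a and miR2118b 95 were higher and 71 lower (290 unadjusted, 143 by DESeq2, 107 and 46 with library totals), between miR2118a and miR2118c 103 and 84 (339 and 174), and between miR2118b and miR2118c 81 and 80 (270 and 145). NBS fragments were 12 of the 95 and 9 of the 71, 11 of the 103 and 12 of the 84, and 11 of the 81 and 11 of the 80. Leaving out single libraries gave 108 to 129, 117 to 166 and 110 to 139 fragments, of which 108 (without miR2118b OX 1) and 117 (without miR2118c OX 2) were below the full count by more than 1.5 times. The kinase-2 lists, chosen after the called fragments were seen, moved apart: in the contrast of b against c, fragments ending in D or N had a median of -0.87 (camera adjusted p 6.22e-05) and those ending in W a median of 2.66 (0.00512). In the contrast of a against c the medians were -0.62 (6.49e-05) and 1.3 (0.0256), and in that of a against b the W list had -1.67 (0.144). With an estimated correlation none of these was called, with adjusted p of 0.19 or more. Single sequences gave 1 higher and 5 lower between a and b (5143 unadjusted, 181 by DESeq2, as 60 and 121, 658 with the replicate block, 0 and 1 with RLE factors), 0 and 2 between a and c (10448, 399, as 92 and 307, and 3629, and 1 and 7 with library totals) and 59 and 101 between b and c (6935, 371 and 2868). These counts fell to 0 when some single libraries were left out, with ranges of 0 to 2, 0 to 8 and 0 to 59.

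**Figure D3:**
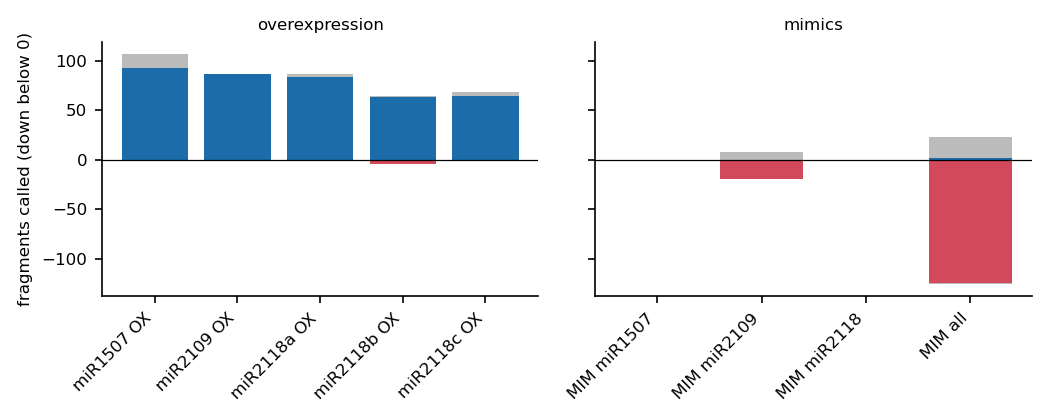
Number of fragments whose 21-nt reads were called higher (blue, above 0) and lower (red, below 0) than the control in each Medicago overexpression and mimic group, by edgeR at an adjusted p under 0.05. Grey parts, above or below 0, are called fragments that had under 2 reads over the 8 untransformed tissues. The bars range from 107 higher and 1 lower in miR1507 OX to 23 higher and 126 lower in the mimic of all 3 miRNAs.

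Whole lists of fragments were then tested in overexpression, to ask whether a class moved. By camera with the preset correlation, 3 of the tests of NBS fragments, phased fragments and predicted targets were called against the control: NBS fragments in miR2118a OX (77 of 166 tested, median 0.15, mean 0.58, adjusted p 0.00872), predicted miR2118 targets in miR2118c OX (7 of 8, median 0.17, mean 1.52, 0.0474, and 0.0617 with the replicate block) and the predicted miR1507 targets in miR2118b OX, which had 1 tested member, c23445 (3.73, 0.00116). With an estimated correlation neither of the lists with more than 1 member was called (adjusted p 0.391 for both). The predicted targets of the family of the overexpressed miRNA were not called in the other constructs, with medians of 0.31 for miR1507 (1 of 6 tested, 0.782), -0.12 for miR2109 (1 of 2, 0.9), and, for the miR2118 targets, 0.19 in miR2118a OX (0.688) and 0.11 in miR2118b OX (0.984). None of the miR2118 sites was predicted for the miR2118b sequence, so that last value does not test targets of its own. Phased fragments were not called in any construct by camera (19 of 21 tested, adjusted p 0.0962 to 0.9). Their medians were below 0, from -0.33 to -0.01, while their means were above 0, from 0.01 to 0.77, and fry called them in miR2118a OX (0.0049), miR2118b OX (0.0233) and miR2118c OX (0.0245). NBS fragments likewise had medians of -0.13 to -0.07 and means of 0.11 to 0.45 in the other 4 constructs (0.592 to 0.782), with fry at 0.0298 in miR2118c OX. With library totals fitted medians near 0 turned sign. NBS fragments went from -0.19 to 0.09 in miR2109 OX and from -0.06 to 0.04 in miR2118c OX. Phased fragments went from -0.07 to 0.34 in miR2118a OX. With library totals the median of all fragments moved by 0.28 in miR2109 OX and 0.41 in miR2118a OX, and by -0.91, -0.15, -0.31 and -0.68 in the mimics of miR1507, miR2109, miR2118 and all. Of the lists chosen after the data were seen, TIR fragments in miR2109 OX had a median of 2.71 (23 of 43 tested, 22 above 0, 18 called, adjusted p 1.21e-32) and were called with an estimated correlation as well (0.00214). Kinase-2 fragments ending in W had a median of 2.33 in miR2118b OX (4 of 9, 0.000392) and those ending in D or N a median of 1.43 in miR2118c OX (12 of 12, 5 called, 1.26e-06), neither called with an estimated correlation (0.139 and 0.184).

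The target mimics were made to lower miRNA activity, and the first question was whether the miRNA itself fell. None of the 28 families tested was called in any mimic, over all sequences or adjusted over the list alone. The miR2109 family had the largest fitted fall, and stood at 26.5 ± 19.2 CPM in MIM miR2109 and 17.2 ± 10.4 in MIM all against 170 ± 41.3 in the control (SD, n = 2), changes of -2.68 (SE 0.75, adjusted p 0.823 over all sequences and 0.229 adjusted over the list alone) and -3.31 (SE 0.77, 0.609 and 0.0882). Their unadjusted p were 0.00818 and 0.00315, and DESeq2 gave adjusted p of 0.0411 and 0.00379, the lowest of ranges over the alternatives that reached 1.0. The miR1507 family stood at 743 ± 242 in MIM miR1507 and 831 ± 70.2 in MIM all against 1450 ± 162 (-0.96 and -0.80, adjusted p 0.675 and 1.0, 0.775 and 0.849 over the list alone). In MIM miR2118 the miR2118 family changed by -0.93 and miR2118b by -1.66 (adjusted p 1.0 for both, 0.763 over the list alone), and in MIM all by -0.54 and -1.98 (1.0 for both, 0.849 and 0.664). For all of these the 2 mimic libraries lay below both controls.

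The mimic of all 3 miRNAs lowered siRNAs on a set of fragments that included 18 with an NBS motif and 13 with a TIR motif. In edgeR 126 fragments were lower and 23 higher of 1556 (384 unadjusted, 188 by DESeq2, as 71 higher and 117 lower). With library totals in place of TMM factors the split was 21 higher and 51 lower. Of the 23 higher fragments 21 had under 2 reads over the untransformed tissues. All of these calls rested on both controls: without MIM control 1 or without MIM control 2 the count was 0, and without MIM all 1 or 2 it was 82 or 63. MIM all 2 stood apart, with 65.6% of its reads outside 21, 22 and 24 nt against 41.4% in MIM all 1, and 11.6% of its 21-nt reads on fragments against 32.4%. The predicted target c16609 fell by 3.06 (SE 0.38, adjusted p 0.0081), from 2.20 ± 0.0785 to 0.245 ± 0.082 CPM, and the predicted target c38502 was at least 2.94-fold lower, with 0 and 0 reads (0.0352). The predicted targets c43087 and c23445 fell by 2.73 (SE 0.52, 0.0178) and 2.20 (SE 0.36, 0.011). The call on c23445 was lost with library totals (0.0593), with no filter (0.0716), with antisense reads only (0.14) and without any 1 of the 4 libraries (0.0503 to 0.12), that on c38502 with only the 2 groups (0.0611), and that on c43087 with library totals (0.069) and antisense reads only (0.305). Of other NBS fragments c53102 fell by 3.02 (SE 0.37, 0.0081), from 16.2 ± 2.04 to 1.98 ± 0.426, c61184 by 2.45 (SE 0.35, 0.0081), c21358 by 3.37 (SE 0.55, 0.011), c20266 by 3.05 (0.0228), c55199 by 2.75 (0.0395) and c57124 by 2.57 (0.0399), and the calls on these last 2 were lost without MIM all 2 and the other library like it, MIM miR1507 2 (0.113 and 0.0889). The phased loci c5429 and c20462 fell by 2.00 (SE 0.36, 0.0161) and 2.73 (SE 0.52, 0.0178), while c1381, at -1.80, and c14947, at -2.04, were not called (0.0596 and 0.101, and c14947 at 0.0496 with the replicate block). With library totals the calls on c61184, c55199, c57124, c5429 and c20462 were lost as well (0.0515 to 0.0843), as was c5429 with no filter (0.137), c20462 with 21 and 22 nt (0.0882) and c57124 with only the 2 groups (0.0611). Fragments c66757, of the TIR class, and c23781 fell by 4.81 (0.0178) and 5.11 (0.0161), and c56182 and c46037 were at least 3.91-fold and 2.11-fold lower (0.0265 and 0.0178, the latter 0.0611 with only the 2 groups). Of all calls named here, only those on c16609 and c53102 held whichever MIM all library was left out. Without MIM all 1 the call was lost on c38502 (0.133), c23445, c21358, c20266, c55199, c57124, c56182, c46037, c23781, c66757, c5429 and c20462 (0.0587 to 0.11), and without MIM all 2 on c38502 (0.0724), c43087 (0.0955), c23445, c20266, c55199, c57124, c61184, c46037, c5429 and c20462 (0.0503 to 0.162). Single sequences gave 0 calls (8482 unadjusted, 1213 by DESeq2, as 934 higher and 279 lower, 0 with the replicate block). Within replicate 1 and replicate 2 the median change of the lower fragments was -1.96 and -2.55 in MIM all and -2.10 and -2.75 in MIM miR2109.

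MIM miR2109 lowered siRNAs on 7 of 19 tested TIR fragments, a list not called with an estimated correlation (0.0706), and the mimics of miR1507 and miR2118 alone gave no calls. In MIM miR2109 19 fragments were lower, of which 7 had a TIR motif, and 8 higher, all 8 with under 2 reads over the untransformed tissues (223 unadjusted, 98 by DESeq2, as 42 higher and 56 lower, and 51 with the replicate block). The TIR fragments c9901 and c43198 fell by 4.69 (SE 0.8, adjusted p 0.0454) and 4.49 (SE 0.71, 0.033), c55612 by 4.27 (0.0454) and c66757 by 3.81 (0.0464), each from under 2 CPM. The calls on c43198 and c55612 were lost with library totals (0.0957 and 0.144) and with only the 2 groups (0.0521 and 0.0601), and those on c55612 and c66757 with 21 and 22 nt (0.0791 and 0.0551). The count was 0 without MIM control 1, MIM control 2 or MIM miR2109 2, and 40 without MIM miR2109 1, with c9901, c55612 and c66757 not among them (0.0755 to 0.143). With library totals in place of TMM factors the split was 18 higher and 3 lower, against 11 and 3 in MIM miR1507 and 0 and 1 in MIM miR2118, and with RLE factors it was 1 and 2 in MIM miR1507. In MIM miR1507 edgeR called 0 fragments (270 unadjusted, 88 by DESeq2, as 59 higher and 29 lower, 3 with the replicate block and 4 without MIM miR1507 2), with c2827 at -2.39 and c20462 at -1.26 (both 0.26). In MIM miR2118 it called 0 as well (130 unadjusted, 53 by DESeq2, as 46 higher and 7 lower), with c16609 at -1.63, c23445 at -1.62 and c20462 at -2.54 (0.142 each, but 0.0127, 0.0319 and 0.0206 with only the 2 groups, 0.024 and 0.0487 by DESeq2 for the first 2, and 0.0223 to 0.0445 without the flat libraries named below), and c5429 at -1.08 (0.348). These 2 controls and 8 mimic libraries included 2, MIM miR1507 2 and MIM all 2, with a flat length profile, and without those 2 libraries MIM miR1507 gave 28 calls and MIM miR2118 gave 30. Single sequences gave 0 calls in edgeR for miR1507, miR2109 and miR2118 (10692, 9347 and 5570 unadjusted, 569, 935 and 497 by DESeq2, of which 525, 674 and 452 were higher and 44, 261 and 45 lower, 0 with the replicate block).

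Lists of fragments were tested in the mimics as well. By camera with the preset correlation, 8 of the tests of NBS fragments, phased fragments and predicted targets were called, all lower: phased fragments in MIM miR1507 (17 of 21 tested, median -0.51, adjusted p 0.013), MIM miR2118 (-0.45, 0.000619) and MIM all (-0.79, 0.00682), NBS fragments in MIM miR1507 (61 of 166 tested, -0.32, 0.0031), MIM miR2109 (-0.14, 0.0174), MIM miR2118 (-0.27, 0.000179) and MIM all (-0.98, 1.35e-09), and the predicted miR1507 targets in MIM miR2118 (2 of 6, -1.71, 0.00353). None was called with an estimated correlation, where the smallest adjusted p was 0.162. Own predicted targets were not called, with medians of -0.15 for MIM miR1507 (0.6), -1.13 for MIM miR2109 (0.201) and -0.33 for MIM miR2118 (0.0909), and -1.49, -2.13 and -1.53 for the 3 target lists in MIM all (0.0705, 0.112 and 0.0638, the last 0.0472 with the replicate block). With its member that had a group at 0 set to the bound, the fitted median of the miR2118 targets in MIM all moved from -1.62 to -1.04. Fragments called higher in overexpression, a list chosen after the data were seen and made from libraries that share no control with the mimics, were lower in the mimic of the same miRNA. Those of miR1507 had a median of -1.34 in MIM miR1507 (62 of 75 below 0, adjusted p 3.61e-18), those of miR2109 a median of -2.55 in MIM miR2109 (70 of 70 below 0, 18 called, 1.86e-50), and those of the miR2118 constructs a median of -0.63 in MIM miR2118 (113 of 140 below 0, 1.75e-20). All 3 were called with an estimated correlation (0.0281 each), but none was with the replicate block (0.0645, 0.0645 and 0.0607). In MIM all the miR2109 list had a median of -3.0 (70 of 70 below 0, 49 called, 8.61e-29, 0.0695 with an estimated correlation) and the miR2118 list a median of -1.42 (125 of 140 below 0, 48 called, 3.14e-24, 0.0281 with an estimated correlation and 0.0607 when the block was added). The miR1507 list in MIM all had a median of -0.28 but a mean of 0.44 and was not called (0.238). With members that had a group at 0 set to their bound, the fitted median of the miR2109 list moved from -3.19 to -3.10. Against another miRNA's mimic, the miR1507 list lay at 0.32 in MIM miR2109 (0.00273, 0.347 with an estimated correlation) and the miR2118 list at -0.28 in MIM miR1507 (109 of 140 below 0, 3.93e-06, 0.176). TIR fragments had medians of -2.91 in MIM miR2109 (17 of 19 below 0, 7 called, 1.73e-13, 0.0706 with an estimated correlation) and -3.33 in MIM all (19 of 19 below 0, 13 called, 8.79e-11, 0.0941). Kinase-2 fragments ending in D or N had medians of -0.65 in MIM miR2118 (0.00175) and -1.67 in MIM all (0.000679), and those ending in W of -1.32 in MIM miR2118 (0.00156), -1.04 in MIM miR1507 (0.0264) and -0.94 in MIM all (0.0991), none called with an estimated correlation (0.067 or more).

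**Figure D4:**
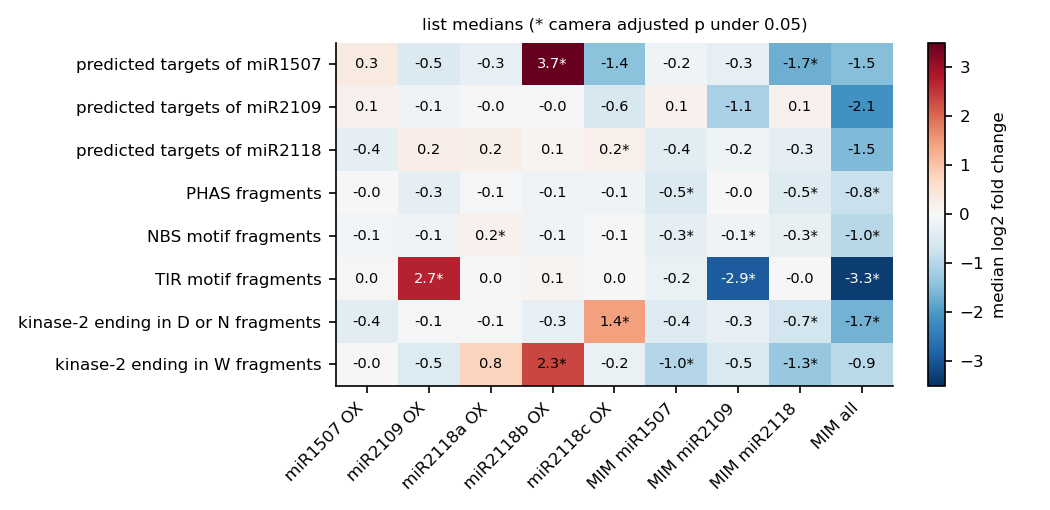
Median log2 change of each fragment list (vertical axis) in each Medicago comparison with its control (horizontal axis), red for higher and blue for lower, with a star where camera with the preset correlation gave an adjusted p under 0.05. TIR fragments had a median of 2.71 in miR2109 OX and of -2.91 in the mimic of miR2109.

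Setting overexpression against mimic asked whether the changes caused by raising and by sequestering the same miRNA differed, in 1 fit of the 22 libraries. For miR1507, 94 fragments had the higher change in overexpression and 10 in the mimic (306 unadjusted, 97 by DESeq2), for miR2109 105 and 18 (269 and 156, the latter as 116 and 40), and for miR2118 24 and 3 (230 and 80, the latter as 47 and 33). Leaving out single libraries gave 72 to 118, 93 to 116 and 4 to 39 fragments, the 4 being without OX control 1 and the 39 without miR2118a OX 1. Of the families, miR2109 differed by 7.26 (SE 1.07, adjusted p 0.0225), and miR1507, by 5.64 (0.183), miR2118, by 3.57 (0.851), and miR2118b, by 4.29 (1.0), were not called. Single sequences gave 115, 225 and 6 calls, as 66 and 49, 204 and 21, and 0 and 6 (338, 1116 and 390 by DESeq2, the last 2 as 542 and 574 and as 65 and 325, 400, 1032 and 92 with the replicate block), and 0 to 48, 0 to 120 and 0 to 9 when single libraries were left out.

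Cleavage was read from PARE tags at predicted sites, in 1 library per group, with no replicate check. The miR1507 site on c14075, at a kinase-2 region, had 441 tags in miR1507 OX (14.0 RPM, 12.7 to 15.4) against 99 in the control (3.06, 2.49 to 3.73), in both the position with most tags on the fragment, and 207 in miR2118a OX (7.15, 6.21 to 8.19). On c19985 the site had 15 tags against 0, on c23445 5 against 0 and on c5174 24 against 2. Over the predicted miR1507 sites, of which 2 of 6 had at least 10 tags over the 6 libraries and entered, the median log2 ratio was 2.76, at the 99.4th percentile of random lists. The miR2109 site on c42795 had 110 tags in miR2109 OX (4.49 RPM) against 48 (1.49), a ratio of 1.59 at the 96.2nd percentile, but 130 in miR1507 OX and 140 in miR2118a OX. Over the 6 of 8 miR2118 sites with at least 10 tags, the median was 0.37 in miR2118a OX (78.6th percentile), -0.03 in miR2118b OX (55.1) and -0.26 in miR2118c OX (26.7). Pooled over those sites the log2 ratios were -0.32, 0.04 and 0.03, with 748 tags in miR2118a OX against 1039 in the control. None of these sites was predicted for the miR2118b sequence, so the values of miR2118b OX do not test sites of its own. Single miR2118 sites moved further. In miR2118a OX c43087 had 71 tags against 10 (2.45 against 0.309 RPM) and c57871 120 against 31 (4.14 against 0.959, with 2.61 in miR2109 OX), and in miR2118c OX c16609 had 16 against 1 (0.496 against 0.0309). The miR2118a OX library was also above the control at sites of other miRNAs, with 4.83 RPM on c42795 and 11.1 against 3.65 on the miR2109 site of c41053. On c12732 the miR2118a site had 976 tags in the control, 30.2 RPM, and from 18.3 in miR2118a OX to 30.8 in the constructs. Cleavage there was high without overexpression. The site on c38502 had 1 tag in miR2118c OX and 2 in the control, and those on c38001 and c34755 had none in the construct or the control. With scores of 5, over the limit, c70984 and c9722 had 26 against 1 and 157 against 16 tags in miR2118c OX.

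The siRNAs that followed cleavage lay in its register on some fragments and not on others, with a share of 4.76% by chance. Of 21-nt reads after position 129 of c16609 in miR2118c OX, 49.6% were in register (2981 of 6006), against 48.1% in the control. On c38502 the share was 68.9% (385 of 559, exact interval 64.9 to 72.7), on c19985 in miR1507 OX 63.4% (1563 of 2465, 61.5 to 65.3) and in its control 78.7% (70 of 89, 68.7 to 86.6). On c12732 it was 73.6% in miR2118a OX (9021 of 12260, 72.8 to 74.4) and 56.9% in the control (2868 of 5037, 55.6 to 58.3). On c23445 the share after the miR1507 position was 63.1% in miR1507 OX (53 of 84) but 2.98% in miR2118b OX (15 of 504, 1.68 to 4.86), where its siRNAs had risen. On c43087, whose tags at the site were 71 against 10 in miR2118a OX, it was 4.19% there (8 of 191, 1.83 to 8.09), and on c19179 it was 0 to 2.42% over the 6 groups. On c5429 it was 17% in miR2118c OX (1080 of 6338) and 13.7% in the control. On c42795 it was 99.3 to 99.6% in all 6 groups, where 98.8% of reads in untransformed tissue were 1 sequence.

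In Arabidopsis leaves each construct raised the introduced miRNA far above the control. The miR1507 family stood at 5070 ± 210 CPM against 4.16 ± 0.0205, a change of 10.25 (SE 0.7, adjusted p 8.28e-07), the miR2109 family changed by 12.23 (SE 0.82, 1.31e-07), to 420 ± 419, and the miR2118 family by 10.45 in miR2118a OX (SE 0.84, 5.7e-06), to 122 ± 111, and by 9.16 in miR2118c OX (SE 0.83, 2.52e-05), to 49.6 ± 32.4. The miR2118b family changed by 9.28 in miR2118b OX (SE 0.65, 6.71e-06), to 16.2 ± 7.3. A run term was chosen after the data were seen. With it the family was not called in miR2109 OX (11, adjusted p 0.55), miR2118a OX (9.27, 0.848) or miR2118c OX (7.98, 1.0). By the exact listed sequence, miR2118 lay at -2.18 in miR2118c OX (0.887), as did miR2118b with 0 and 0 reads against 0 and 1. This does not show a fall: the family, pooling a and c, had 500 and 1636 reads there. The controls shared a run with miR1507 OX, and their 93 and 112 miR1507 reads set a background. In the other run miR2109 OX and miR2118a OX had 0 reads. Native families rose too. In miR2109 OX these were miR398 by 2.58 (0.00551), miR408 by 2.16 (0.00858), miR169 by 1.49 (0.00551), miR397 by 3.13 (0.029) and miR399 by 1.27 (0.0486), and in miR2118c OX miR398 by 2.70 (0.00344), miR408 by 2.23 (0.00531), miR169 by 1.54 (0.00354), miR399 by 1.59 (0.0118), miR397 by 3.17 (0.0228) and miR156 by 1.23 (0.0445). miR397, miR398 and miR408 are known to respond to copper and miR399 to phosphate. Both constructs lay in the other run than the controls. Adjusted over the list alone, miR169 and miR398 rose in all constructs, also in miR1507 OX, of the controls' run. Of 33 families, 1, 6, 1, 1 and 7 were higher in miR1507, miR2109, miR2118a, b and c OX over all sequences, and 3, 8, 5, 3 and 8 adjusted over the list alone, and 1 family, miR1507, was lower in miR2109, miR2118a and miR2118c OX.

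Single Arabidopsis sequences changed in numbers that differed widely between constructs. The test was edgeR on 50725 sequences. All libraries of miR2109, miR2118a and miR2118c OX lay in the other run than the controls and miR1507 OX. Only miR2118b OX had 1 library in each run, and a run term rested on that pair. In miR1507 OX 95 were higher and 23 lower (3451 unadjusted, 130 by DESeq2), in miR2109 OX 1424 and 117 (6737 and 881), in miR2118a OX 38 and 13 (3691 and 129), in miR2118b OX 48 and 2 (3528 and 78) and in miR2118c OX 1572 and 129 (6616 and 1080). With the run term the counts were 9, 0, 22 and 1 for miR2109 and miR2118a, b and c, and the term itself was called for 37 sequences one way and 6 the other. With library totals in place of TMM factors miR2109 OX gave 277 higher and 342 lower, miR2118a OX 16 and 10 and miR2118c OX 593 and 153. Controls decided much of this: without control 2 or control 1 the counts were 25 and 31 for miR1507, 175 and 218 for miR2109, and 4 and 18 for miR2118b, and every left-out library took miR2118a to between 2 and 19. For miR1507 OX the count was 39 without replicate 1, for miR2109 OX 559 without replicate 2, for miR2118b OX 320 without replicate 2, and for miR2118c OX it ranged from 236 without replicate 1 to 4068 without replicate 2, with 298 and 393 without a control. In miR1507 OX the leading sequence, ATAGAGATCGAGCAGCTTGTT, had 97 and 125 reads against 0 and 0 (adjusted p 9.08e-05), AACCGAATTGAGACTGTTGTC 75 and 90 (0.000291), ACTCGGATTCGCTGACTTGGA 71 and 74 (0.000467) and ATTGATGATGACTCTAAAAGA 74 and 67 (0.000501), and no other construct had a read of any of the 4. Of its 94 higher sequences outside the families 40 were of 20 to 22 nt. In miR2118b OX GTTACTGATTGTTGTTTAATGCAG rose by 5.23 (SE 0.48, 2.95e-05), to 4.01 ± 0.92 CPM, with 608 reads in the other constructs, and ATATATAGAACTTGATGACGAGAA had 31 and 36 reads against 0 and 0 (0.0178) and none in the others. In miR2118a OX AAATGAGAGTATCGTTGCGCC had 42 and 18 against 0 and 0 (0.0298) and TCGAGATTGCTTTGGCCATGG 25 and 20 (0.0282), with 2 and 12 reads in the others. In miR2118c OX CTTTAAGTACTTTTTCGGGCATT had 50 and 12 reads (0.0044), and 118 in the others. The other leading sequences of miR2109 and miR2118c OX carried the stretch CAGACCGGTAG, which lay in 24.6 to 30.6% of the 20 to 24-nt reads of every Arabidopsis library. Of the sequences higher in these constructs, 1205 of 1418 and 1304 of 1565 were of 23 to 24 nt. Contrasts between the miR2118 constructs gave 3, 6 and 4 sequences for a against b, a against c and b against c (2561, 3914 and 3003 unadjusted, 3, 13 and 10 by DESeq2, the last as 1 higher and 9 lower, and 1 higher and 2 lower for a against c with library totals). Without single libraries these were 2 to 73, 0 to 357 and 4 to 701.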

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

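Of the tests of explanations in this part, those of read length, of the flat libraries, of an absent mimic effect, of the controls' share of reads and of a shared vector part, and the comparison set of that last test, were chosen only after the result was seen.

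A difference between groups, tested as a difference of changes between overexpression and mimic, marked the fragments of miR1507 (104), miR2109 (123) and miR2118 (27), the single sequences (115, 225 and 6) and the miR2109 family (7.26). Direct contrasts between miR2118 constructs marked 166 fragments for a against b, 187 for a against c and 161 for b against c.

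Many more Arabidopsis sequences were higher in miR2109 OX and miR2118c OX than in miR1507 OX, and the construct is mixed with the run. If the run were the cause, at least 75% of the 1934 sequences were predicted to be higher in miR2118b OX 1, of their run, than in miR2118b OX 2, of the run of the controls, and at most 60% if not, and the share was 63.1% (60.9 to 65.3), which cannot tell. In miR2118a OX, with both libraries in that run, 38 were higher, which goes against the run as the whole cause, but the direct contrast of miR2118a with miR2118c OX called only 6, so a difference between those 2 was not shown. A shift in read length stays open as a cause. With sequences of 21 to 22 nt alone the smaller of the 2 counts was 3.03 times that of miR1507 OX. Over all lengths the counts were 1424 and 1572 against 95. Such a shift can change sequences of 21 to 22 nt too, so the test cannot exclude it. With a run term the counts over all lengths were 9, 0, 22 and 1 for miR2109 and miR2118a, b and c OX. That term, resting on the 2 miR2118b libraries, was called for 37 and 6. An effect of the constructs on native small RNAs was not separated from the run.

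With edgeR at an adjusted p under 0.05 there was no call on fragments in MIM miR1507 or MIM miR2118. Without the 2 libraries of flat length profile the smaller of the 2 counts was 28, over the 10 predicted if those libraries hid the calls. That the mimics had no effect on siRNAs of their own miRNA was argued against by fragments called higher in overexpression, which lay below 0 in both mimics, with the larger of the 2 unadjusted camera p with an estimated correlation at 0.00905 and, with the replicate block, at 0.0215. Adjusted over the lists, that p was 0.0281 in both mimics and with the block 0.0645 and 0.0607, over the threshold. The count without the flat libraries cannot tell whether they hid calls, because it rests on a lone MIM miR1507 library. MIM miR2118 kept both of its libraries, neither of them flat, so its added calls came through the shared fit. The argument against an absent effect rests on the unadjusted p, and the lists were not called once both the block and the adjustment were applied.

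Of the sequences higher in Medicago miR1507 OX, 270 occurred in transformed Arabidopsis but in no untransformed tissue. Of their Arabidopsis reads 12.5% (10.8 to 14.5) lay in miR1507 OX, which excluded reads from the miR1507 construct alone, for which at least 75% was predicted. A test written before the values were seen predicted at most 30% for carry-over between libraries. A part shared by the constructs predicts the same spread, so the value does not separate them. The 2 Arabidopsis controls held 10.6% as many of these reads as the miR1507 OX libraries of their run, against at least 75% predicted for an even carry-over. That test covers few of the 1275 reads, 17 in the controls and 160 in miR1507 OX. It says nothing about the other run. The other Medicago overexpression groups held at least 56.5 times the control reads, but these sequences were chosen against that control, and 225 others chosen in the same way with no Arabidopsis reads gave 26.5 to 62.1 times, so a shared vector part stays open. So does carry-over in the other run.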

How the results depend on the processing

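The mimic fits without 2 libraries, the run term, the fragment level and the blocked list tests were chosen only after the results were seen. With 2 libraries per group, a left-out library leaves a lone sample that is assumed to vary like the other groups. The depth of 11.2 to 48.3 M reads and the assembly from control roots limit which loci could be seen. Unless said otherwise the cause of a difference was not tested. Of 1963 repeats of 150 values of named fragments, 1801 gave the same call, 12 passed the threshold only there, 150 lost it and 0 turned direction. DESeq2 kept 142 of the 150, RLE factors 150, the replicate block 147 and library totals 140. Predicted targets with a score of at most 3 were not run for miR2118, and own sites of the miR2118b sequence were not run at any score, because there were none.

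By fragments, same-numbered Medicago libraries correlated at -0.126 to 0.341 over 15 pairs in overexpression and -0.019 to 0.602 over 10 pairs in the mimics. The numbers did not pair the Arabidopsis libraries (-0.203 to 0.137 over 15 pairs). With the replicate block fragments gave 111, 92, 91, 77 and 79 in miR1507, miR2109, miR2118a, b and c OX, 168, 201 and 172 between the miR2118 constructs, 3, 51, 0 and 176 in the mimics of miR1507, miR2109, miR2118 and all, and 119, 131 and 36 in overexpression against mimic. With the block, sequences gave 3761, 880, 687, 905 and 3266 in overexpression, 658, 3629 and 2868 between the constructs, 0 in each mimic, and 400, 1032 and 92 in overexpression against mimic. The families gave 4.69 (0.0113), 4.47 (0.00718), 4.36 (0.0061), 7.03 (0.000392) and 3.59 (0.00628) for miR1507, miR2109, and miR2118 in a, b and c. Of the list tests the block moved the predicted miR2118 targets from 0.0474 to 0.0617 in miR2118c OX and from 0.0638 to 0.0472 in MIM all, and moved the fragments of overexpression in the mimics, with an estimated correlation, from 0.0281 to 0.0607 to 0.0645. By fry it moved phased fragments in MIM miR1507 from 0.0336 to 0.0611, kinase-2 fragments ending in W from 0.11 to 0.00498 in miR1507 OX and from 0.158 to 0.0423 in miR2118a OX, and predicted miR1507 targets from 0.0473 to 0.055 for a against c. It changed no other call.

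With DESeq2 fragments gave 88, 98 and 53 in the mimics of miR1507, miR2109 and miR2118, and 80 in overexpression against mimic of miR2118. Sequences gave 1368, 501, 403, 462 and 758 in overexpression, 181, 399 and 371 between the constructs, 569, 935, 497 and 1213 in the mimics, 338, 1116 and 390 in overexpression against mimic, and in Arabidopsis 881, 129, 78 and 1080 for miR2109 and miR2118a, b and c, and 13 and 10 for a against c and b against c. Families gave 4.76 (1.48e-09), 4.58 (3.44e-11), 4.38 (2.83e-11), 7.22 (2.92e-16) and 3.51 (6.35e-07) in overexpression, and for miR2109 -2.68 (0.0411) in MIM miR2109 and -3.29 (0.00379) in MIM all. Over all alternatives the adjusted p of each of these families reached 1.0.

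With library totals fragments gave 14, 1 and 72 in the mimics of miR1507, miR2118 and all. Sequences gave 165, 142 and 238 in miR2109, miR2118a and miR2118b OX, 20 and 8 for a against b and a against c, and in Arabidopsis 619, 26, 22 and 746 for miR2109 and miR2118a, b and c, and 3 for a against c. Families gave 4.73 (0.00509), 4.71 (0.019), 4.65 (0.0177), 7.19 (0.0105) and 3.72 (0.0153). RLE factors gave 3 fragments in MIM miR1507 and 1 sequence for a against b. With no filter the mimics of miR1507, miR2109 and miR2118 gave 52, 71 and 44 fragments. Sequences with no filter gave 3849, 845, 700, 1179 and 3961 in overexpression, 657, 4377 and 3906 between the constructs, 31, 29, 15 and 36 in the mimics, and in Arabidopsis 790, 2952, 813, 552 and 3279, and 80, 274 and 378 between constructs.

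With only the 2 groups compared, MIM miR1507 and MIM miR2118 gave 14 and 55 fragments. Sequences gave 1200, 0 and 0 in miR1507, miR2118b and miR2118c OX, 0, 0 and 0 between the constructs, 2333 in MIM miR2109, and in Arabidopsis 372, 516 and 109 for miR1507, miR2118a and miR2118b and 7 for a against b. Without the 2 flat libraries the mimics of miR1507, miR2109 and miR2118 gave 28, 99 and 30 fragments. Antisense reads alone gave 55 in miR2118a OX, 110 for a against b, 14 in MIM miR1507 and 92 in MIM all, reads with up to 20 places 19 and 42 in MIM miR1507 and MIM miR2109, and reads of 21 and 22 nt 12 in MIM miR2109. Arabidopsis sequences of 21 to 22 nt alone gave 39, 102, 13, 25 and 150, and 1 for a against c. The run term gave 9, 0, 22 and 1 sequences in Arabidopsis, 2 for b against c, and families of 11 (0.55), 9.27 (0.848) and 7.98 (1.0) for miR2109 and for miR2118 in a and c, the highest adjusted p over the alternatives in which their direction held. The exact listed sequence gave -2.18 (0.887) for miR2118 in c.

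Camera with an estimated correlation called 0 of the tests of NBS, phased and target lists in place of 3 in overexpression and 0 in place of 8 in the mimics, and fry called 8 in overexpression. Targets with a score of at most 3 gave 1 list in overexpression and a PARE median of 2.19 for miR1507, and a score of at most 5 gave 3.33 for miR1507 and 0.584 for miR2118a. Phasing thresholds of 1e-04 and 1e-10 gave 60 and 3 phased fragments. Per 21-nt reads the tissue ratios were 116, 16.5, 4210 and 1220 for miR1507, miR2109, miR2118 and miR2118b.

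Leaving out each library in turn, fragments ranged from 54 to 94, 52 to 81, 31 to 74, 39 to 49 and 44 to 88 in miR1507, miR2109, miR2118a, b and c OX, 108 to 129, 117 to 166 and 110 to 139 for a against b, a against c and b against c, 0 to 4, 0 to 40, 0 to 0 and 0 to 82 in the mimics of miR1507, miR2109, miR2118 and all, and 72 to 118, 93 to 116 and 4 to 39 in overexpression against mimic. Sequences ranged from 0 to 348, 0 to 0, 0 to 0, 0 to 2 and 0 to 570 in overexpression, 0 to 2, 0 to 8 and 0 to 59 between the constructs, 0 to 0 in each mimic, and 0 to 48, 0 to 120 and 0 to 9 in overexpression against mimic. In Arabidopsis they ranged from 25 to 80, 175 to 1502, 2 to 19, 4 to 320 and 236 to 4068, and between constructs 2 to 73, 0 to 357 and 4 to 701. Fewer libraries are the construction of these repeats, and the cause of each rise was not tested. The studied families kept their direction in every one, and in Arabidopsis their calls, with 3.44 to 5.47, 3.66 to 5.09, 3.77 to 4.76, 5.62 to 8.08 and 3.27 to 3.87 in Medicago overexpression, and in Arabidopsis 10.20 to 10.29, 10.52 to 13.23, 8.97 to 11.24, 8.55 to 11.44 and 8.30 to 9.93. The median level in polyadenylated RNA ranged from 1.5 to 1.52. All calls of named fragments in MIM miR2109 and MIM all were lost without MIM control 1 or MIM control 2, with adjusted p of 0.311 to 0.374 and 0.339 in MIM miR2109 and of 0.0926 to 0.172 and 0.106 to 0.29 in MIM all.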

Other observations

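The test of phasing in this part was chosen only after the result was seen.

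Among the untransformed tissues, siRNAs of several phased loci were highest in leaves. The APETALA2-like fragment c14947 and the auxin-receptor-like fragment c365 were both highest in leaves, and the aldo-keto reductase-like c2827 was as well, with 8.27 RPM against 0.04 in 16-dpi nodules. The TIR-NB-LRR-like c6652 had 21.4 RPM in leaves and 3.89 in roots. The miR169 family stood at 805 RPM in flowers. Fragment c42795, whose reads are almost all 1 sequence, held 412 to 1810 RPM in the 7 tissues other than flowers.

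Arabidopsis sequences higher in miR1507 OX that had no reads in Medicago joined into a stretch of 156 nt. It held 621 reads of 21 nt in miR1507 OX over 81 positions, and 0 in the controls and other constructs. The leading (largest) register held 38.6%, mostly the 97 and 125 reads of 1 called sequence. A frame of it reads like the end of the nucleotide-binding domain of an NB-LRR, which would make it a candidate transcript for siRNAs that follow miR1507. For phased siRNAs a score of at least 3 was predicted and under 1.3 otherwise, and the score was 1.88, so neither share nor score could tell.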
